A study of Mus musculus with 26 samples.

How the data were processed

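RNA-seq libraries of sorted LSK cells from CML mice were analysed: 26 libraries in 5 groups (global KO 6, Spred1 wt, HSC KO, HSC wt and EC KO 5 each), grouped by the titles and genotype labels. The deposited table holds raw read counts per gene and library, as whole numbers without normalization. According to the submitters' processing notes, bcl2fastq 2.18.0.12, STAR 2.6.0, HTSeq 0.6.0 and edgeR 3.28.1 were used with build mm10. The annotation and the strand setting of counting are not stated, so that counts of overlapping genes and of paralogs (globin, histone and ribosomal protein genes) are uncertain. The table has 24091 genes, of which 5297 have 0 counts in all libraries, and 0 mitochondrial-chromosome genes, so that 1 of the 37 lists fixed, which consisted of such genes, was not tested. All 26 columns were mapped to samples and 0 pairs of columns were identical. Of the gene symbols, 23325 matched the reference annotation, 95.6% of them with an end within 5 kb of it. Coordinates are those of the table.

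Total counts lay between 14816100 and 26714300 per library. A count of 0 allows up to 3 counts, and this floor covers counting error only. The analysis used R 4.3.3, Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9. Levels are CPM with TMM-scaled library sizes (edgeR 4.0.16), and log2 CPM for principal components and list means used a prior count of 2. After filterByExpr (minimum count 10, 5 groups), 13379 genes were tested. All 26 libraries entered 1 fit of the group means with 21 residual degrees of freedom and a biological coefficient of variation of 0.205. Each comparison was a contrast of the edgeR quasi-likelihood F-test with robust dispersion, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes. The comparisons were global KO against Spred1 wt, HSC KO against HSC wt, EC KO against Spred1 wt (in place of EC wt, not analysed here), HSC wt against Spred1 wt, and the difference of the first 2 effects. Standard errors come from the same fit. The overlap of calls was counted per direction, and its Fisher's exact test is not used, because the 1 shared gene was the one knocked out.

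Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 36 lists of a comparison, with the same test at an estimated correlation and with fry beside it. The lists cover signalling, stress, metabolism, the cell cycle, cell death and markers of cell types of the bone marrow. List means per library were compared by exact permutation of the libraries. A library was read as female from Xist of at least 500 CPM and as male from Y-linked genes of at least 20 CPM.

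Groups, comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule took Spred1 and Egfl7, the 10 genes with the largest rises and falls among those passing with a mean of at least 5 CPM in the higher group (or the 5 smallest p in a direction with fewer than 3), and the 4 members of smallest p of each passing list. It also took 3 members each of the ERK output, RAS-MAPK, BCL2 family, haematopoietic stem cell and interferon-stimulated lists. The text names mostly 1 to 3 members per list, a narrowing chosen after the values were seen. Mir674, Meis2, DQ267101, Spint1, Slamf9, Ccnd1 in the controls, and Mtrr and Fastkd3 in HSC KO lie outside the rule and were chosen after their values were seen, as were the genes named for the principal components. Some genes that the rule took are not reported here, though they stayed in every fit, list and count.

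Alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile normalization, no filter and a filter of 1 CPM in 5 libraries, a fit of the compared groups only, limma voom with sample quality weights, a sex-gene covariate, a log2 threshold of 1, each library left out in turn, and HSC wt or the mean of both wild-type groups as control for EC KO. Alternatives chosen after seeing the data were covariates for mast cell and macrophage transcripts, libraries with Y transcripts only, gene length correction, gene length and GC correction (GC known for 99.4% of tested genes), counts without genes within 20 Mb of Spred1, and exact permutation of list means. Regroupings drew 100 splits of the libraries per comparison.

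The analysis was tested on simulated data with known changes in 200 genes. At true changes of 1.5, 2 and 4-fold it found 79.1%, 88.1% and 98.5% of changed genes in the global KO design, 67.2%, 89.6% and 93.9% in HSC KO, 61.2%, 88.1% and 98.5% in EC KO and 73.1%, 83.6% and 98.5% in the controls. In the difference it found 40.3%, 80.6% and 89.4%. Of calls, 2.75%, 2.91%, 6.25%, 3.95% and 2.10% were false in these 5 designs, among 13278 to 13300 genes. The 1 simulated list was recovered and 0 others were called. Simulated genes varied independently of each other, and libraries differed only by the planted changes and depth. The simulation therefore cannot show how often genes or lists are falsely called where genes vary together, as in the real libraries.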

Results

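RNA was sequenced from LSK cells, the lineage-negative, Sca-1-positive and c-Kit-positive fraction of bone marrow that holds stem and multipotent progenitor cells. The cells came from mice with SCLtTA/BCR-ABL, an inducible transgenic model of chronic myeloid leukaemia (CML), and gave 26 libraries in 5 groups. The groups differed in Spred1, which codes for a membrane-bound inhibitor of RAS-ERK signalling. The global KO group (6 libraries) carried the knockout in all cells and had the Spred1 wt group (5 libraries) as its control. The HSC KO and HSC wt groups (5 libraries each) had Mx1-cre activated with 7 doses of 250 µg poly(I:C), an inducer of interferon, given every 2 days. The EC KO group (5 libraries) carried the endothelial knockout. Its control, EC wt, is not among the samples and was not analysed here, so Spred1 wt stood in for it. Whether the Spred1 wt, global KO and EC KO mice received poly(I:C) is not stated. The labels speak of mice, and p-values below measure the spread between libraries, each read as 1 mouse.

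Total counts per library ranged from 16010400 to 20399100 in global KO, 14816100 to 20197400 in Spred1 wt, 15824700 to 18895700 in HSC KO, 16284200 to 26714300 in HSC wt and 18487600 to 24114800 in EC KO, to 6 digits. All 6 global KO and all 5 Spred1 wt libraries held transcripts of Y-linked genes. Xist, the X-inactivation transcript of female cells, marked 3 HSC KO, 2 HSC wt and 2 EC KO libraries. The first principal component held 32.01% of the variance. Mast cell genes such as Tpsab1 and Cma1 lay at its high end and macrophage and erythroid genes such as C1qa and Slc4a1 at its low end, and each knockout group held libraries with positive and with negative scores.

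Spred1 (mm10, chromosome 2, 117121071 to 117182277) was lower in every knockout group. It stood at 32.7 ± 7.36 CPM (read counts scaled to library size; mean ± SD, n = 6) in global KO and at 114 ± 20.7 (n = 5) in Spred1 wt, and it fell by 1.81 on the log2 scale (SE 0.146, edgeR adjusted p = 2.86e-08, lower than all controls in 6 of 6 libraries). In HSC KO it stood at 35.4 ± 7.29 against 104 ± 4.90 CPM in HSC wt (n = 5 each) and fell by 1.55 (SE 0.154, edgeR adjusted p = 4.14e-06, 5 of 5 libraries). In EC KO it stood at 70.4 ± 11.4 CPM (n = 5) and fell by 0.70 against Spred1 wt (SE 0.150, edgeR adjusted p = 0.00527, 5 of 5 libraries). The 2 wild-type groups did not differ past the threshold in Spred1, at a log2 difference of -0.14 (edgeR adjusted p = 0.92). The single libraries stood at 22.4, 44.5, 28.1, 33.1, 33.1 and 34.7 CPM in global KO and at 92.4, 106, 148, 110 and 115 CPM in Spred1 wt. They stood at 28.8, 47.4, 36.7, 32.8 and 31.3 CPM in HSC KO, at 96.9, 109, 106, 107 and 101 CPM in HSC wt and at 84, 80.9, 58, 63 and 66 CPM in EC KO. Mir674, a microRNA gene at 117185127 to 117185226, just past the end of Spred1, had 3 counts in all 5 Spred1 wt libraries together. It stood at 0.708 ± 0.364 CPM in global KO and 0.0388 ± 0.0581 in Spred1 wt, and it rose in 6 of 6 libraries (edgeR adjusted p = 0.00077).

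**Figure D1:**
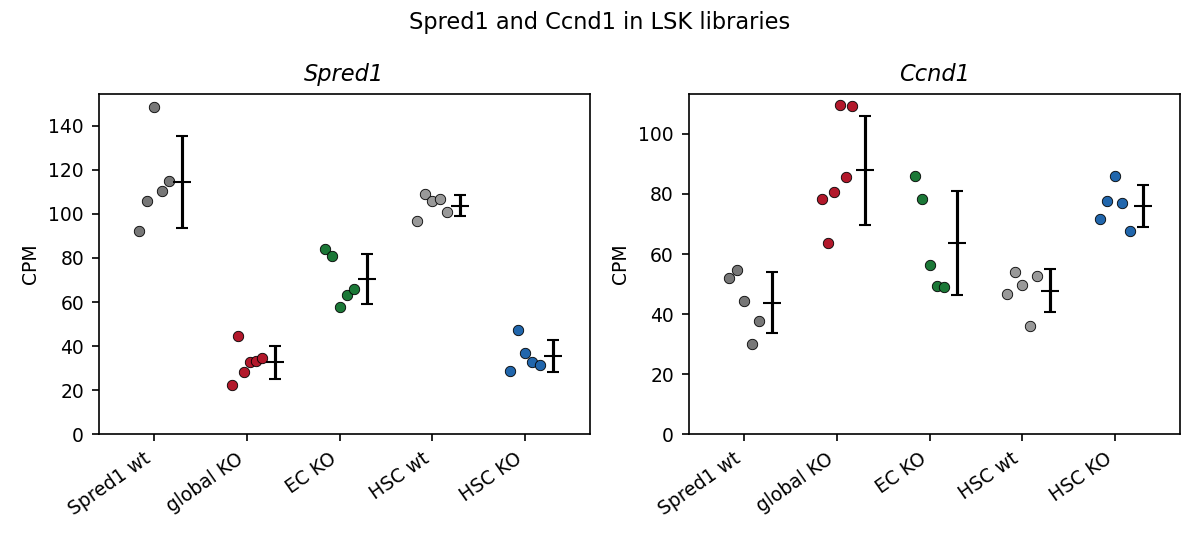
CPM of Spred1 and Ccnd1 in each library (points) of the 5 groups on the horizontal axis, with bars for the mean ± SD. Spred1 was lowest in global KO (32.7 ± 7.36) and HSC KO (35.4 ± 7.29), where Ccnd1 stood at 87.8 ± 18.2 and 76.0 ± 6.92.

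The comparison of global KO with Spred1 wt asked which transcripts of leukaemic LSK cells follow the loss of Spred1 in all tissues. Ccnd1, which codes for cyclin D1, a driver of the step from G1 into S phase and a known output of ERK signalling, rose 2.01-fold (log2 difference 1.004, SE 0.171, edgeR adjusted p = 0.00738). Its level was 87.8 ± 18.2 CPM in global KO (n = 6) and 43.7 ± 10.2 in Spred1 wt (n = 5), and all 6 knockout libraries lay above all controls. Mtrr, which codes for methionine synthase reductase, fell by 0.98 (14.1 ± 1.15 against 27.8 ± 3.15 CPM, edgeR adjusted p = 2.23e-09, 6 of 6 libraries). Fastkd3, a mitochondrial RNA-binding protein gene that lies next to Mtrr on chromosome 13, fell by 1.11 (11.2 ± 1.64 against 24.2 ± 0.974 CPM, edgeR adjusted p = 3.71e-07, 6 of 6 libraries).

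In all, 3 genes rose and 7 fell among 13379 tested, with 740 genes at an unadjusted p under 0.05 where chance alone gives 669. Spred1 and 4 other genes that fell lie on chromosome 2, as does Mir674, which rose. Kcnip3, a calcium-binding partner of potassium channels, fell by 3.22 (1.08 ± 0.273 against 10.1 ± 5.49 CPM, edgeR adjusted p = 4.53e-05, 5 of 6 libraries below all controls). Sqrdl, a mitochondrial sulfide oxidase, fell by 1.01 (9.27 ± 2.04 against 18.7 ± 3.27 CPM, edgeR adjusted p = 0.00831, 6 of 6). Spg11 fell by 0.62 (37.8 ± 2.24 against 57.9 ± 11.3 CPM, edgeR adjusted p = 0.00471, 3 of 6). Meis2, a homeobox gene, fell from 2.40 ± 1.75 to 0.193 ± 0.139 CPM (edgeR adjusted p = 0.0239, 2 of 6). Without any of global KO 1, 3, 4 or 5 or Spred1 wt 3, 4 or 5 the Meis2 call was lost, with adjusted p from 0.0673 without global KO 1 to 0.124 without global KO 4. St6galnac2, a sialyltransferase gene, was at 0 in global KO 2 and between 7.19 and 13.1 CPM in the other 5 knockout libraries, against 0.0589 ± 0.0677 CPM in Spred1 wt (edgeR adjusted p = 0.000293). H2-T10 (log2 difference 0.86, edgeR adjusted p = 0.121), Inafm2 (0.28, 0.172) and Tgif2 (0.38, 0.243) had the next smallest p among genes with higher levels and did not pass. H2-T10 passed without global KO 5 (adjusted p = 0.014) or Spred1 wt 2 (0.0486), Inafm2 without Spred1 wt 1 (0.00234) and Tgif2 without Spred1 wt 2 (0.0486). Egfl7, the host gene of miR-126, stood at 67.9 ± 15.8 against 50.8 ± 17.2 CPM (edgeR adjusted p = 0.897).

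The ERK output genes, which include feedback inhibitors induced by ERK, passed camera upward in global KO (13 of 15 members higher, median log2 difference 0.29, camera adjusted p = 3.37e-06). The call was lost with an estimated correlation (adjusted p = 0.18 with an estimated correlation). Only Ccnd1 rose by itself, both over all genes and adjusted over the list alone. Spry4 (log2 difference 0.86), Etv5 (0.49) and Spry2 (0.35) did not pass (edgeR adjusted p = 0.562, 0.647 and 0.805). The list mean lay above all controls in 4 of the 6 global KO libraries and below all controls in the other 2 (exact permutation p = 0.134, 0.788 adjusted over lists).

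**Figure D2:**
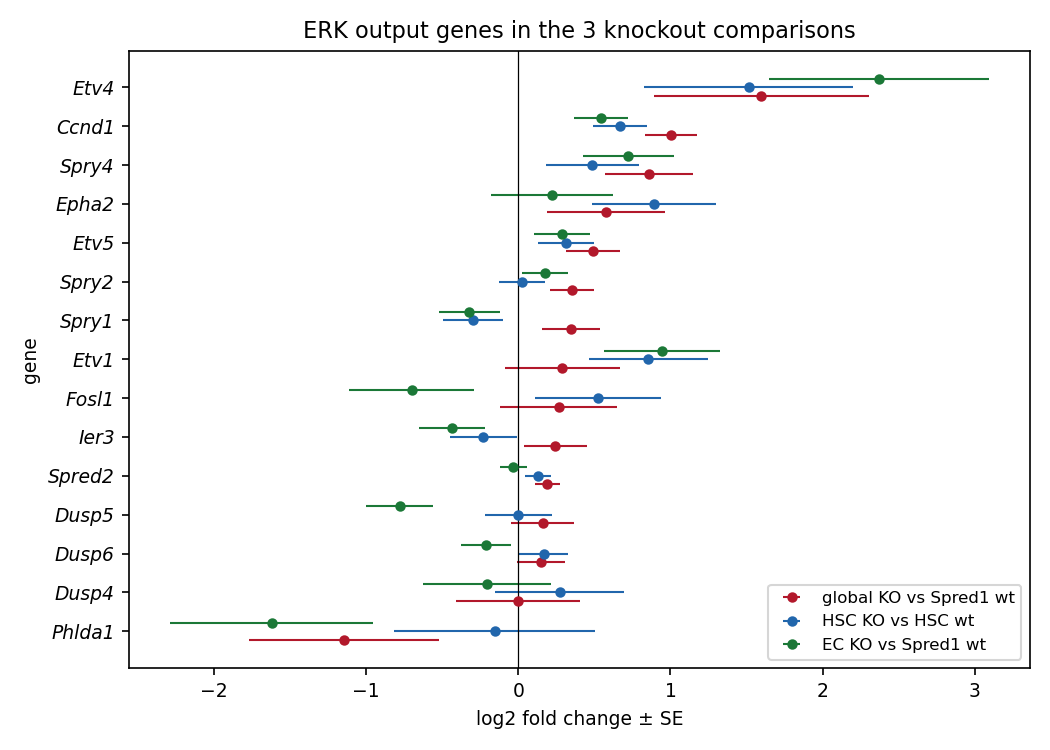
Log2 fold change with its standard error (bars) of 15 ERK output genes on the vertical axis in 3 knockout comparisons. Ccnd1 lies at 1.004 in global KO, 0.67 in HSC KO and 0.54 in EC KO.

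The mature neutrophil markers passed camera downward (11 of 12 lower, median -2.00, camera adjusted p = 2.08e-11; adjusted p = 0.178 with an estimated correlation). Of them, 7 fell adjusted over the list alone and 0 over all genes. Ltf, a granule protein gene, stood at 2.93 ± 4.16 against 27.5 ± 28.4 CPM, and Ly6g at 0.0194 ± 0.0304 against 0.619 ± 0.699. The list mean was below all controls in 3 of 6 libraries. Ribosomal protein genes passed upward (75 of 77 higher, median 0.11, camera adjusted p = 1.96e-12; adjusted p = 0.848 with an estimated correlation), with Rps20 at 0.23 and Rpl9 at 0.17. Cholesterol synthesis genes passed upward (15 of 16 higher, camera adjusted p = 7.13e-05; adjusted p = 0.376 with an estimated correlation), among them Fdft1 (0.24). In both of these lists 0 members passed over the list alone.

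The unfolded protein response genes passed downward (camera adjusted p = 0.000129; adjusted p = 0.773 with an estimated correlation), with Chac1 at -2.77 and Ddit3 at -0.47 and 1 member falling over the list alone, but not without Spred1 wt 4 (adjusted p = 0.322). The p53 target genes passed downward (camera adjusted p = 0.00579; adjusted p = 0.178 with an estimated correlation), with Fas, a death receptor gene, at -0.70 and Eda2r at -0.97, but not without Spred1 wt 3 (0.0521). The histone genes passed upward (camera adjusted p = 0.00343; adjusted p = 0.967 with an estimated correlation), with Hist1h2ae at 0.76, but not without global KO 6 (0.421) or Spred1 wt 2 (0.0879). The mast cell and basophil markers passed downward (camera adjusted p = 0.0164; adjusted p = 0.848 with an estimated correlation), with Gzmb at -1.16 but Prss34 at 1.06, and not without global KO 3 (0.112), global KO 6 (0.153) or Spred1 wt 3 (0.175). The plasma cell markers passed downward with the same camera adjusted p = 0.0164 (adjusted p = 0.848 with an estimated correlation), with Mzb1 at -0.999, and not without global KO 2 (0.243), global KO 5 (0.0906), Spred1 wt 1 (0.229) or Spred1 wt 2 (0.103). The RAS-MAPK components (median 0.03, camera adjusted p = 0.525), BCL2 family genes (0.02, 0.948), interferon-stimulated genes (-0.13, 0.0786) and haematopoietic stem cell genes (0.01, 0.813, tested downward with a mean of -0.01) did not pass, nor did the other 23 lists.

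The count of 10 rose to 21 without global KO 2, 25 without Spred1 wt 1 and 24 without Spred1 wt 2, and DESeq2 called 45. A fit of these 11 libraries alone called 4 genes, and Ccnd1, Spg11, Sqrdl and St6galnac2 were not among them.

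The comparison of HSC KO with HSC wt asked what follows the loss of Spred1 through Mx1-cre, with poly(I:C) given to both groups. Apart from Spred1, 2 genes fell and 0 rose. Of these, DQ267101, a transcript of the imprinted Dlk1-Dio3 region of chromosome 12, fell by 1.91 on the log2 scale (0.296 ± 0.0403 against 1.12 ± 0.362 CPM, n = 5 each, edgeR adjusted p = 0.00584, 5 of 5 libraries below all controls). Meg3, the long noncoding RNA of the same region, stood at 5.77 ± 2.57 against 16.3 ± 4.67 CPM (5 of 5 lower, edgeR adjusted p = 0.801), and passed in DESeq2. Ccnd1 stood at 76.0 ± 6.92 against 47.9 ± 7.17 CPM, a log2 difference of 0.67 (SE 0.175) with all 5 knockout libraries above all controls, but did not pass (edgeR adjusted p = 0.999).

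There were 289 genes at an unadjusted p under 0.05, fewer than the 669 of chance alone, and DESeq2 called 5, all falling. Among genes with higher levels, Ccnd2 (0.23), Itgal (0.31), Btnl9 (0.43) and Hbb-b2 (1.57) followed Ccnd1 and did not pass (edgeR adjusted p = 0.999 for each). Among lower ones, Arhgef28 (-0.82, edgeR adjusted p = 0.402) and Kcnk5 (-0.52, 0.999) did not pass. Mir674 had 0.510 ± 0.197 against 0.0770 ± 0.0414 CPM, higher in 5 of 5 libraries (edgeR adjusted p = 0.159). Mtrr stood at 30.0 ± 1.06 against 30.2 ± 1.64 CPM and Egfl7 at 54.2 ± 4.72 against 48.9 ± 7.71, both with edgeR adjusted p = 0.999. With libraries that hold Y transcripts alone (2 HSC KO and 3 HSC wt) 0 genes passed. Spred1 still had a log2 difference of -1.33 there, with fewer libraries in the test (edgeR adjusted p = 0.119).

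Of 36 lists, 18 passed camera in HSC KO and 0 passed with an estimated correlation (0.48 to 0.608 among these 18). In brackets below, the camera adjusted p stands before that with an estimated correlation. The haematopoietic stem cell genes passed downward (17 of 19 lower, median -0.26, camera adjusted p = 9.47e-08; adjusted p = 0.521 with an estimated correlation). Their examples were Esam (-0.56), Prdm16 (-0.57) and Fgd5 (-0.71), and the list mean lay below all controls in 3 of 5 libraries. The immediate early genes passed downward too (18 of 19 lower, camera adjusted p = 5.67e-06; adjusted p = 0.521 with an estimated correlation), with Fos at 666 ± 281 against 1009 ± 400 CPM and Fosb at 829 ± 373 against 1307 ± 573. The ERK output genes passed upward (12 of 15 higher, median 0.27, camera adjusted p = 0.000845; adjusted p = 0.521 with an estimated correlation), with Etv4 at 1.51, Epha2 at 0.89 and Etv1 at 0.86, but only Ccnd1 rose adjusted over the list alone. The ribosomal protein genes (77 of 77 higher, median 0.08, camera adjusted p = 2.71e-07; adjusted p = 0.561 with an estimated correlation) and oxidative phosphorylation genes (21 of 21, median 0.15, 3.83e-07; 0.521) passed upward, with Rpl4 at 0.10 and Ndufa4 at 0.19. So did the S phase genes (16 of 16 higher, 0.000341; 0.521) and G2 and M phase genes (20 of 20, 0.000121; 0.521), with Rrm1 at 0.13 and Aurkb at 0.17, the latter list not without HSC wt 1 (0.0677) or HSC wt 2 (0.0569). The mature neutrophil markers (median -0.85, camera adjusted p = 0.000201; adjusted p = 0.521 with an estimated correlation) and the HOXA-MEIS genes (7 of 7 lower, 0.00722; 0.521) passed downward, with Mmp8 at -0.95 and Meis1 at -0.28.

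The remaining 9 lists passed camera in HSC KO only with particular libraries in the fit, and 0 of their members passed over the list alone. The erythroid markers passed upward (adjusted p = 0.0248; 0.561 with an estimated correlation), but 1 library, HSC KO 1, carried the signal of Alas2, a heme synthesis gene (3.605 ± 7.89 against 0.337 ± 0.179 CPM), and without it the list turned downward (0.169). Without HSC wt 4 (0.0919) or HSC wt 5 (0.0512) that call was also lost. The plasma cell markers passed upward (0.00777; 0.521), with Jchain at 1.56, and turned downward without HSC KO 1 (0.778). The macrophage and monocyte markers passed upward (0.00753; 0.521), with C1qa at 1.47, and not without HSC KO 1 (0.0951) or HSC KO 4 (0.112). The genes of MHC class II presentation passed upward (0.0248; 0.561), with Cd74 at 1.21, and not without HSC KO 1 (0.911), HSC KO 3 (0.0916), HSC wt 4 (0.102) or HSC wt 5 (0.082). Those of MHC class I presentation passed upward (0.0484; 0.521), with Psmb9 at 0.14, and not without HSC KO 1 (0.719), HSC wt 3 (0.279), HSC wt 4 (0.0996) or HSC wt 5 (0.0589). The endothelial cell markers passed upward (0.0493; 0.521), with Plvap at 0.70, and not without HSC KO 1 (0.265), HSC KO 3 (0.0572), HSC wt 4 (0.13) or HSC wt 5 (0.10). Their list mean lay above all controls in 5 of 5 libraries (exact permutation p = 0.007937, the smallest that 252 regroupings allow, 0.2857 adjusted over lists). The BCL2 family genes passed upward (0.0248; 0.48), with Bid, a death agonist, at 0.24, and not without HSC KO 3 (0.0572) or HSC wt 5 (0.0716). The unfolded protein response genes passed upward (0.0493; 0.608), with Asns at 0.46, and not without HSC KO 1 (0.19), HSC KO 2 (0.097), HSC KO 5 (0.0661), HSC wt 1 (0.48) or HSC wt 2 (0.211). The cholesterol synthesis genes passed downward (0.0176; 0.521), with Insig1 at -0.20, and not without HSC KO 1 (0.0926), HSC KO 4 (0.0505), HSC KO 5 (0.182) or HSC wt 5 (0.0753). The RAS-MAPK components (median 0.04, camera adjusted p = 0.375), interferon-stimulated genes (0.21, 0.224) and the other 16 lists did not pass.

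The difference between the global KO and HSC KO effects was tested as an interaction of the 4 groups. Mtrr and Fastkd3 differed: their log2 differences of effects were -0.98 (SE 0.099, edgeR adjusted p = 5.48e-06) and -1.23 (SE 0.148, edgeR adjusted p = 8.37e-05), with levels of 30.0 ± 1.06 and 26.3 ± 2.58 CPM in HSC KO (n = 5) and 14.1 ± 1.15 and 11.2 ± 1.64 in global KO (n = 6). Mtrr and Fastkd3 are neighbours on chromosome 13, so that they may not be 2 separate differences. Whether a chromosome segment of another origin in the global KO libraries, rather than the loss of Spred1, lowered both was not tested. Kcnip3 (-3.02, edgeR adjusted p = 0.0929) did not pass. Kcnip3 passed without Spred1 wt 1 (0.000141), and St6galnac2 (7.20, 0.996) without global KO 2 (0.00775). There were 286 genes at an unadjusted p under 0.05, and the count of 2 rose to 4 without global KO 2 and 7 without Spred1 wt 1. DESeq2 called 7 and limma voom 5. The calls of the 2 comparisons shared 1 gene that fell, Spred1, the gene knocked out in both, so that its overlap tests no shared response, and log2 differences correlated across genes with Pearson's r of 0.149 and Spearman's rho of 0.177.

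In the test of the difference 12 lists passed camera and 0 with an estimated correlation, whose adjusted p stands second in brackets below. The cholesterol synthesis genes (16 of 16 more positive in global KO, camera adjusted p = 1.10e-07; adjusted p = 0.319 with an estimated correlation) and haematopoietic stem cell genes (15 of 19, 0.000366; 0.53) were relatively higher in global KO. The unfolded protein response genes (14 of 14 more negative, 9.66e-07; 0.38) and G2 and M phase genes (0.000366; 0.611) were relatively lower. The plasma cell markers were relatively lower (1.92e-05; 0.38), with 4 members passing over the list alone, but not without HSC KO 1 (0.0579). The mature neutrophil markers were relatively lower (0.00118; 0.53), but not without Spred1 wt 1 (0.152) or HSC wt 5 (0.0588). The oxidative phosphorylation genes were relatively lower (0.00118; 0.767), but not without Spred1 wt 3 (0.0606). The HOXA-MEIS genes were relatively higher (0.00857; 0.53), but not without global KO 6 (0.0695) or Spred1 wt 4 (0.0571). The T and NK cell markers were relatively lower (0.0109; 0.38), with 1 member passing over the list alone, but not without global KO 2 (0.122) or HSC KO 1 (0.22). The immediate early genes were relatively higher (0.00467; 0.767) and lost the call without any of 6 libraries, from 0.06 without Spred1 wt 2 to 0.32 without Spred1 wt 3, with global KO 2 (0.158), global KO 6 (0.0994), HSC KO 1 (0.104) and HSC wt 2 (0.0942) between. The interferon-stimulated genes were relatively lower (0.00857; 0.777), lost the call without global KO 2 (0.106), global KO 4 (0.127), global KO 5 (0.0527), Spred1 wt 1 (0.117), Spred1 wt 2 (0.06) or HSC wt 3 (0.0521), and turned without HSC KO 1 (0.255). The granulocyte-monocyte progenitor genes were relatively lower (0.0455; 0.758) and lost the call without 10 libraries, from 0.0519 without global KO 5 to 0.369 without Spred1 wt 4, with global KO 2 (0.0684), 4 (0.078) and 6 (0.198), Spred1 wt 1 (0.0645), HSC KO 4 (0.0898) and 5 (0.137), and HSC wt 1 (0.229) and 2 (0.196) between. The ERK output genes did not differ past the threshold (median 0.08, camera adjusted p = 0.155), though they passed without global KO 1 (0.0347), global KO 3 (0.0213), HSC KO 2 (0.0367) or HSC wt 5 (0.0451). The RAS-MAPK components (median -0.02, mean 0.00, tested upward, camera adjusted p = 0.92) and BCL2 family genes (0.125) did not pass either.

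The comparison of EC KO with Spred1 wt asked how LSK cells differ after the loss of Spred1 in endothelial cells, with a stand-in control. Spred1 was itself lower in the EC KO LSK cells, as given above. An effect through endothelial cells therefore cannot be told apart from lower Spred1 within LSK cells or from the choice of control. Serinc3, a transmembrane protein gene of chromosome 2, stood at 170 ± 4.59 CPM in EC KO (n = 5) against 2007 ± 216 in Spred1 wt (n = 5), an 11.8-fold lower level (log2 difference -3.56, SE 0.085, edgeR adjusted p = 1.93e-20, 5 of 5 libraries). Ncmap, a myelin-associated protein gene, rose by 5.40 on the log2 scale, from 0.161 ± 0.144 to 7.15 ± 1.36 CPM (edgeR adjusted p = 2.17e-07). Rida rose by 1.28 (33.2 ± 3.85 against 13.7 ± 1.76 CPM, edgeR adjusted p = 1.58e-08) and Ncf4, a subunit of the phagocyte NADPH oxidase, by 1.04 (109 ± 8.96 against 52.9 ± 5.38 CPM, edgeR adjusted p = 1.55e-08), each in 5 of 5 libraries. Atp8b5, a lipid flippase gene, fell from 33.2 ± 17.5 to 0.683 ± 0.233 CPM (edgeR adjusted p = 1.25e-05), and Kcng1, a potassium channel gene, from 5.65 ± 4.36 to 0.0480 ± 0.0683 (edgeR adjusted p = 0.000145). Of these 6 genes, Serinc3 and Kcng1 (chromosome 2), Ncmap and Atp8b5 (chromosome 4) and Rida (chromosome 15) lie in bins of 10 Mb that held more calls than the genome, and Ncf4 lies outside them.

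In all, 467 genes rose and 598 fell, of which 34 and 118 by at least 2-fold, with 3360 genes at an unadjusted p under 0.05. Srd5a1, a steroid reductase gene, rose by 1.45 (edgeR adjusted p = 0.000145), Kif21a, a kinesin gene, by 1.30 (0.00482) and Depdc7 by 1.26 (0.00216), each in 5 of 5 libraries. Hmga2, a chromatin protein gene of fetal stem cells, rose by 1.11 (11.1 ± 2.22 against 5.13 ± 2.12 CPM, edgeR adjusted p = 0.013) but stood at 12.3 ± 3.48 CPM in HSC wt, and against that group its log2 difference was -0.15. Kcnip3 fell by 3.81 (edgeR adjusted p = 5.02e-06), Epas1, a hypoxia-inducible factor gene, by 2.81 (0.000686), Ednra, an endothelin receptor gene, by 2.67 (0.00794, 4 of 5 libraries below all controls) and Dnm3 by 2.91 (0.0139). Ccnd1 stood at 63.8 ± 17.3 against 43.7 ± 10.2 CPM (log2 difference 0.54, edgeR adjusted p = 0.0554, 3 of 5 above all controls), and passed without Spred1 wt 2 (0.0477), EC KO 4 (0.0478) or EC KO 5 (0.0297) and in DESeq2. Egfl7 stood at 62.3 ± 13.5 against 50.8 ± 17.2 CPM (edgeR adjusted p = 0.38). Mir674 had 0.221 ± 0.0222 CPM and rose in 5 of 5 libraries (edgeR adjusted p = 0.0265), though not without Spred1 wt 2 (0.075), Spred1 wt 3 (0.0577), Spred1 wt 4 (0.0547) or EC KO 3 (0.051).

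**Figure D3:**
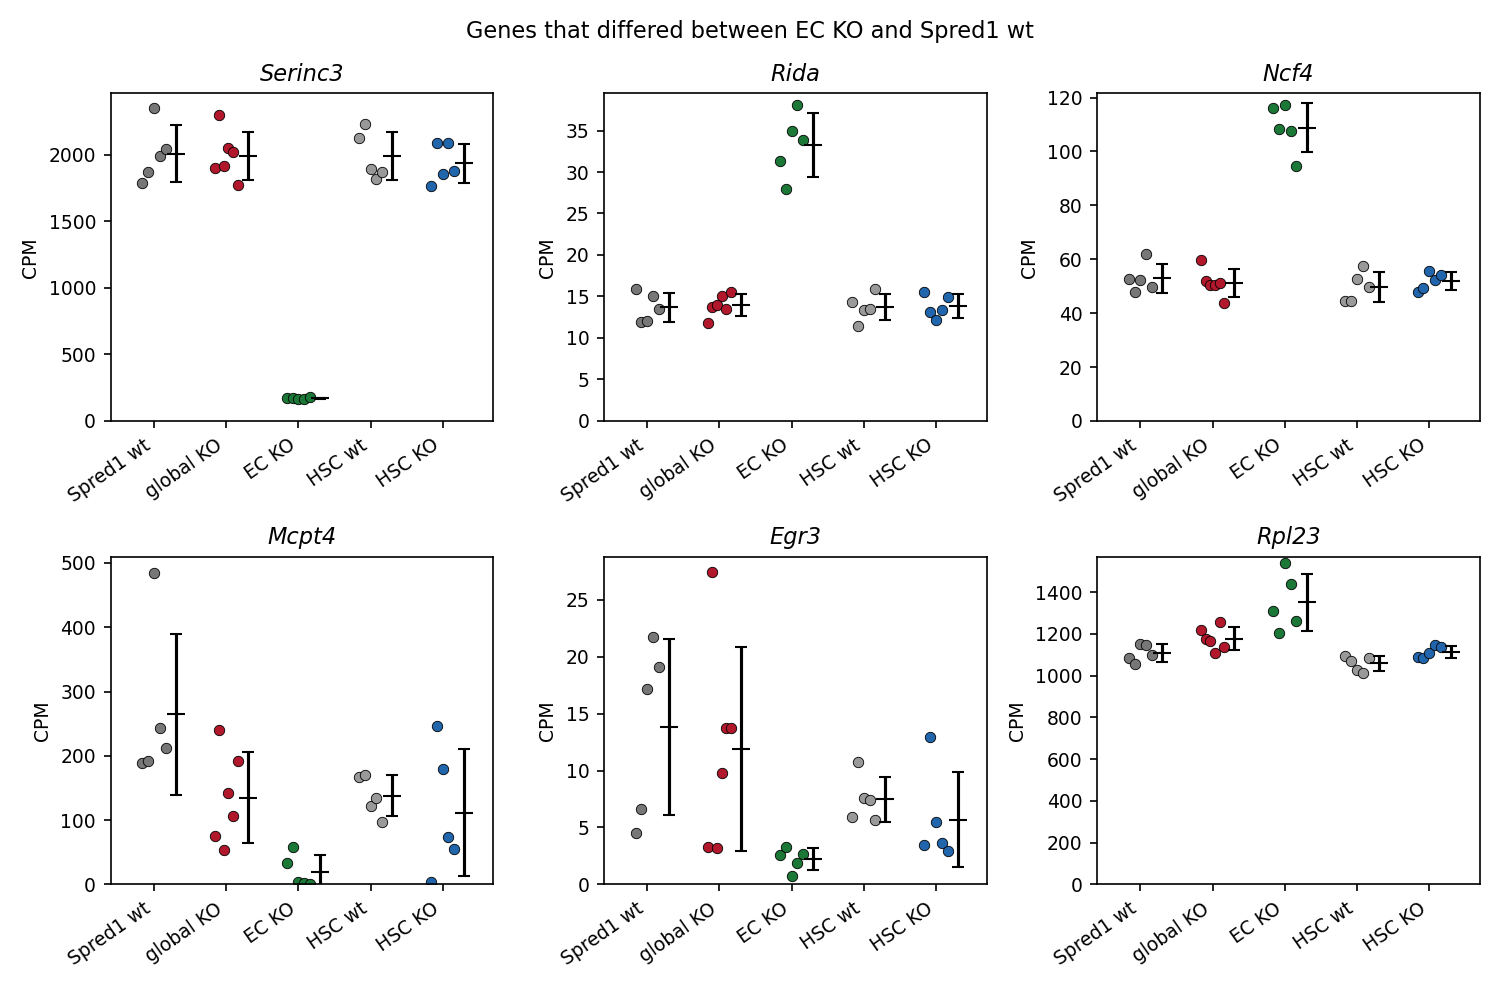
CPM of 6 genes in each library (points) of the 5 groups on the horizontal axis, with bars for the mean ± SD. Serinc3 lies at 170 ± 4.59 in EC KO and between 1934 ± 147 and 2007 ± 216 in the other groups, and Mcpt4 spreads from 3.56 to 247 within HSC KO.

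Ribosomal protein, oxidative phosphorylation, histone and S phase genes passed camera upward in EC KO. Of 77 ribosomal protein genes, 31 rose over all genes and 62 adjusted over the list alone, where 2 fell (median 0.26, camera adjusted p = 4.37e-18; adjusted p = 0.782 with an estimated correlation; fry 0.0419). Rpl22l1 rose by 0.53 (185 ± 25.2 against 128 ± 16.05 CPM, edgeR adjusted p = 0.00138) and Rpl23 by 0.29 (1352 ± 138 against 1109 ± 41.8 CPM, 0.00303). Of 21 oxidative phosphorylation genes, 5 rose over all genes and 11 over the list alone (camera adjusted p = 1.13e-06; adjusted p = 0.782 with an estimated correlation), with Ndufb3, a complex I subunit gene, up by 0.53 (edgeR adjusted p = 0.00239). With a gene length correction the ribosomal list still passed, while the oxidative phosphorylation list (camera adjusted p = 0.07049), Rpl22l1 (edgeR adjusted p = 0.0975) and Rpl23 (0.09706) did not. Of 53 histone genes, 5 rose over all genes and 6 over the list alone (4.38e-05; 0.782), with Hist1h4m up by 2.40 (edgeR adjusted p = 0.00523). Of 16 S phase genes, 3 rose over all genes and 4 over the list alone (7.57e-05; 0.782), with Slbp, the histone mRNA-binding protein gene, up by 0.29 (edgeR adjusted p = 0.0069).

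Immediate early and inflammatory genes and PI3K-AKT-mTOR components passed camera downward in EC KO. All 19 immediate early genes had lower levels, and 3 fell over all genes and 6 over the list alone (median -0.82, camera adjusted p = 1.58e-06; adjusted p = 0.782 with an estimated correlation). Egr3 fell by 2.61 (2.25 ± 0.962 against 13.8 ± 7.77 CPM, edgeR adjusted p = 0.00639, 5 of 5 libraries). Of 17 NF-kB and inflammatory genes, all lower, 1 fell over all genes and 3 over the list alone (camera adjusted p = 0.000534; adjusted p = 0.782 with an estimated correlation; fry 0.0419), with Nfkb2 down (log2 difference -0.49, edgeR adjusted p = 0.00924). Of 19 PI3K-AKT-mTOR components, 4 fell over all genes and 7 over the list alone (camera adjusted p = 0.000534; adjusted p = 0.307 with an estimated correlation; fry 0.000618), with Mtor down (-0.27, edgeR adjusted p = 0.00746). With a gene length correction the list did not pass (camera adjusted p = 0.4241), nor did Mtor (edgeR adjusted p = 0.2501). The p53 target genes passed in fry alone (fry adjusted p = 0.0419, camera 0.114).

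The mast cell and basophil markers and the interferon-stimulated genes passed camera downward in EC KO, with members on both sides. Of 10 mast cell and basophil markers 3 were higher and 2 fell (camera adjusted p = 0.026; adjusted p = 0.782 with an estimated correlation), among them Mcpt4 (19.8 ± 25.7 against 265 ± 125 CPM, edgeR adjusted p = 0.013, 5 of 5 libraries), while Mcpt8, another protease gene, stood at 598 ± 346 against 279 ± 43.8 CPM and did not pass (edgeR adjusted p = 0.1691). The group was split: the list mean (log2 CPM) lay below all controls in EC KO 3, 4 and 5 (6.003, 5.827 and 5.872), the libraries with Y transcripts, and among the controls (7.698 to 9.659) in EC KO 1 and 2 (8.157 and 8.168), the libraries with Xist. The macrophage and monocyte markers stood at 4.271, 3.735 and 4.173 in EC KO 3, 4 and 5 and at 2.453 and 1.875 in EC KO 1 and 2. The mast cell and basophil list did not pass without Spred1 wt 3 (0.0736), Spred1 wt 4 (0.0626), Spred1 wt 5 (0.0539) or EC KO 5 (0.0936). Of 26 interferon-stimulated genes 1 fell (camera adjusted p = 0.0286; adjusted p = 0.834 with an estimated correlation), Oasl2, at 8.93 ± 6.40 against 36.1 ± 11.2 CPM (edgeR adjusted p = 0.00665), and the list did not pass without Spred1 wt 1 (0.174), Spred1 wt 2 (0.0667), Spred1 wt 4 (0.0626), EC KO 1 (0.19) or EC KO 2 (0.166). The mean of the interferon list lay below all controls in EC KO 1 and 2 (2.990 and 3.125), the libraries with Xist. It lay among the controls (3.734 to 4.366) in EC KO 3, 4 and 5. Against HSC wt, Isg15 (log2 difference 0.297) and Zbp1 (0.375) had higher levels in EC KO and did not pass. Of the ERK output genes, Etv4 rose and Dusp5, an ERK phosphatase gene, fell, and the list did not pass (median -0.03, mean 0.06, tested downward, camera adjusted p = 0.936). Etv4 (edgeR adjusted p = 0.0437) lost the call without Spred1 wt 1 (0.0863), 2 (0.0975) or 5 (0.107) or EC KO 1 (0.113), 2 (0.101) or 3 (0.063), and Dusp5 (0.0278) without Spred1 wt 4 (0.0542) or 5 (0.0619) or EC KO 2 (0.0625), 3 (0.0836) or 4 (0.0553). The RAS-MAPK components (camera adjusted p = 0.725), haematopoietic stem cell genes (0.156), BCL2 family genes (0.554) and the other 22 lists did not pass.

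The count of 1065 fell to 483 without EC KO 3, 628 without EC KO 4 and 584 without Spred1 wt 5, and stood at 1880 without EC KO 5. It was 333 in a fit of these 10 libraries alone, 671 with a sex-gene covariate, 692 with a gene length correction and 2514 with covariates for mast cell and macrophage transcripts, 684 of them among the 1065. With HSC wt as the control, Serinc3, Rida and Ncf4 still passed, while Kcnip3 (edgeR adjusted p = 0.8506), Depdc7 (0.8393), Hist1h4m (0.8202), Nfkb2 (0.1395) and Dnm3 (0.1081) did not.

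The comparison of HSC wt with Spred1 wt showed how far 2 wild-type groups differ. Kcnip3 fell by 3.65 on the log2 scale (0.802 ± 0.304 against 10.1 ± 5.49 CPM, n = 5 each, edgeR adjusted p = 9.78e-05, 5 of 5 libraries). Spint1, a protease inhibitor gene, fell by 2.10 (edgeR adjusted p = 0.0249, 2 of 5), Sqrdl by 1.04 (9.12 ± 1.49 against 18.7 ± 3.27 CPM, 0.0376, 5 of 5) and Slamf9 by 2.34 (0.0386, 5 of 5). Kcnip3, Spint1 and Sqrdl lie on chromosome 2, within 20 Mb of Spred1, and Slamf9 on chromosome 1.

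**Figure D4:**
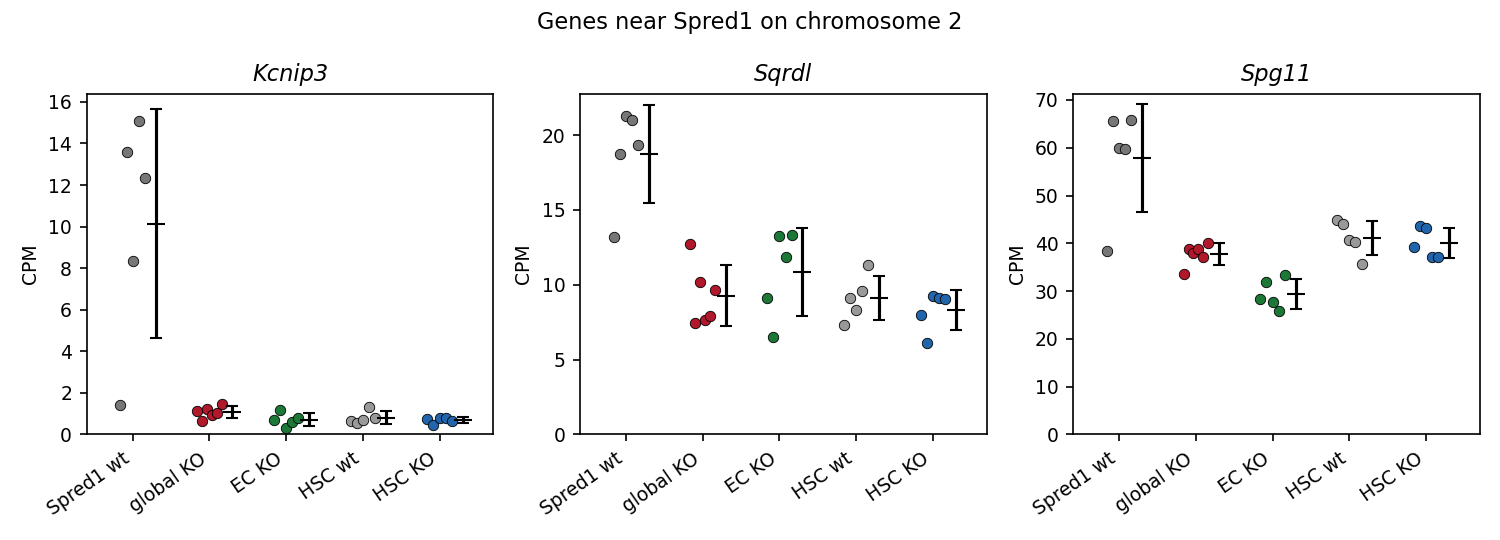
CPM of Kcnip3, Sqrdl and Spg11 in each library (points) of the 5 groups on the horizontal axis, with bars for the mean ± SD. Kcnip3 stands at 10.1 ± 5.49 in Spred1 wt and at 0.802 ± 0.304 in HSC wt, and Spred1 wt 1 (1.41) lies near the other groups.

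The controls had 0 genes that rose, with 850 genes at an unadjusted p under 0.05, and DESeq2 called 35 and limma voom 18. Hmga2 (1.26, edgeR adjusted p = 0.123), Depdc7 (1.17, 0.104), Pak6 (0.96, 0.15) and Hist1h1e (0.95, 0.174) had higher levels in HSC wt, and Emp1 (-1.65, 0.123), Spg11 (-0.49, 0.123) and Eif3j1 (-0.84, 0.174) lower ones, without passing. Without Spred1 wt 1, Hmga2 (0.00897), Pak6 (0.0467), Spg11 (0.00051) and Eif3j1 (0.00051) passed. Ccnd1 stood at 47.9 ± 7.17 against 43.7 ± 10.2 CPM (edgeR adjusted p = 0.95). The call of Spint1 was lost without Spred1 wt 2 or 3 or any HSC wt library (adjusted p up to 0.1336, without HSC wt 3). That of Sqrdl was lost without Spred1 wt 2, 3, 4 or 5 or HSC wt 1, 2, 3 or 4 (up to 0.1396, without HSC wt 1), and that of Slamf9 without Spred1 wt 2 or 4 or any HSC wt library (up to 0.1899, without Spred1 wt 4). A fit of these 10 libraries alone called 1 gene, which was none of these 4. The count of 4 stood at 21 without Spred1 wt 1, at 2 without Spred1 wt 3, Spred1 wt 4 or HSC wt 5, and at 1 without HSC wt 1, 2, 3 or 4.

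Between the 2 wild-type groups 17 lists passed camera and 0 with an estimated correlation, whose adjusted p stands second in brackets below. The interferon-stimulated genes were lower in HSC wt, the group given poly(I:C) (24 of 26 lower, median -0.50, camera adjusted p = 2.77e-07; adjusted p = 0.419 with an estimated correlation). Zbp1 stood at 5.57 ± 0.749 against 12.8 ± 4.60 CPM, Isg15 at 2.57 ± 0.853 against 5.66 ± 2.11, and the list mean lay below all Spred1 wt libraries in 5 of 5. The plasma cell markers (6 of 6 lower, 4.57e-07; 0.211), unfolded protein response genes (14 of 14, 8.62e-07; 0.222), NF-kB and inflammatory genes (15 of 17, 7.35e-05; 0.222) and p53 target genes (12 of 13, 0.000304; 0.0897; fry 0.0231) were lower, with Mzb1 at -1.78, Trib3 at -1.39, Ccl3 at -0.86 and Sesn2 at -0.48. The mature neutrophil markers (11 of 12 higher, 2.77e-07; 0.211), histone genes (38 of 53, 0.00015; 0.521) and cholesterol synthesis genes (14 of 16, 0.000232; 0.249) were higher, with Mmp8 at 1.64 and Hist1h4m at 2.22 among the first 2 lists. Over the list alone 3 plasma cell, 3 unfolded protein response and 1 NF-kB gene fell, while 1 neutrophil and 3 histone genes rose.

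The other 9 lists that passed between the controls depended on single libraries. The ribosomal protein genes (8.14e-05; adjusted p = 0.638 with an estimated correlation; Rps24 at -0.21) did not pass without Spred1 wt 3 (0.112), and the macrophage and monocyte markers (0.000304; 0.40; Cd68 at -0.40) did not without Spred1 wt 1 (0.0913). The oxidative phosphorylation genes (0.0112; 0.638; Ndufa1 at -0.31) did not pass without Spred1 wt 3 (0.196), Spred1 wt 4 (0.0859), HSC wt 1 (0.291) or HSC wt 2 (0.0681). The RAS-MAPK components, which were higher (0.0178; 0.222), with Nf1, a RAS GTPase activator, at 0.24, did not without Spred1 wt 1 (0.11), Spred1 wt 2 (0.0682) or HSC wt 3 (0.0627). The BCL2 family genes (0.0188; 0.172; fry 0.0231; Bcl2l11 at -0.18) did not without Spred1 wt 4 (0.0647) or Spred1 wt 5 (0.0612). The genes of MHC class II presentation (0.0215; 0.521; Cd74 at -1.50) did not without Spred1 wt 1 (0.252), Spred1 wt 2 (0.092) or HSC wt 4 (0.0621). The lymphoid-primed progenitor genes (0.0383; 0.475; Il7r at -0.94) did not without Spred1 wt 1 (0.128) or 2 (0.211) or HSC wt 3 (0.111), 4 (0.113) or 5 (0.0595). The microRNA biogenesis genes, which were higher (0.0406; 0.222; Dgcr8 at 0.09), did not without Spred1 wt 1 (0.133), 2 (0.0687) or 3 (0.0934) or HSC wt 3 (0.0508) or 4 (0.0797). The genes of MHC class I presentation (0.0416; 0.521; B2m at -0.42, 1 falling over the list alone) did not without Spred1 wt 1 (0.0601), 2 (0.151) or 3 (0.191) or HSC wt 3 (0.169) or 4 (0.0673). The ERK output genes did not pass (median -0.23, camera adjusted p = 0.205) except without HSC wt 2 (0.0389), and the haematopoietic stem cell genes did not (median -0.01, tested upward, 0.856).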

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

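Of the explanations weighed here, those on read depth, on the spread of the length trend and on endothelial loss of Spred1 were written before their results were seen, and all others after. Of 378 groups of values 22 held a library far from the others, where chance flags about 1 in 20 groups (18.9). Single libraries stood apart from the rest of their group in the following values.

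In the global KO group, St6galnac2 was at 0 CPM in global KO 2. Spred1 wt 1 had low Kcnip3 (1.411 CPM), Spg11 (38.41) and Sqrdl (13.21). Spred1 wt 3 had Bcl2 at 127.6, Cd68 at 43.94, Mcpt4 at 484.7 and Rps24 at 1839 CPM, and Spred1 wt 5 had Bbc3 at 9.56. HSC KO 1 had high Alas2 (17.73 CPM), Kdr (2.857) and Psmb9 (73.88). Btnl9 was at 5.397 CPM in HSC KO 2, Spred2 at 55.24 in HSC KO 4, and Bid at 78.81 and Msmo1 at 19.51 in HSC KO 5. In HSC wt 2, Isg15 was at 4.077 and Spred2 at 49.1 CPM. In HSC wt 3, Alas2 was at 0.04641, Shc1 at 126.2 and Sqle at 37.03 CPM, and in HSC wt 4 Mtrr was at 33.04.

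The effects of global KO and HSC KO differed by a test of the difference for Fastkd3 (-1.23 on the log2 scale) and its neighbour Mtrr (-0.98). For this pair a chromosome segment of another origin was not tested. They also differed by camera for the cholesterol synthesis genes (adjusted p = 1.10e-07), unfolded protein response genes (9.66e-07), plasma cell markers (1.92e-05), haematopoietic stem cell genes (0.000366) and G2 and M phase genes (0.000366). The same held for the mature neutrophil markers (0.00118), oxidative phosphorylation genes (0.00118), immediate early genes (0.00467), interferon-stimulated genes (0.00857), HOXA-MEIS genes (0.00857), T and NK cell markers (0.0109) and granulocyte-monocyte progenitor genes (0.0455). With an estimated correlation 0 of these 12 lists passed (adjusted p from 0.319 to 0.777), and the interferon-stimulated genes turned direction without HSC KO 1 (0.2551).

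Genes near Spred1 on chromosome 2 were over-represented among small p-values wherever Spred1 wt was the control, though less so in EC KO. The odds ratio of an edgeR p under 0.001 for genes within 20 Mb of Spred1 against others was 15.7 in global KO and 3.02 in EC KO. Between the 2 wild-type groups, neither of which lacks Spred1, that odds ratio was 26.8 (95% confidence interval 12.5 to 54.6). This argues against the loss of Spred1 as the cause there. The interval counts genes as independent observations, though neighbours may vary together in the same libraries. It therefore measures no spread between mice. Of the 36 neighbours with a p under 0.01, 75% had Spred1 wt 1 as the Spred1 wt library closest to HSC wt. That is the result predicted if some Spred1 wt mice carry a chromosome segment of another origin. Chance gives 20% only if the libraries are interchangeable and the genes independent, and genes elsewhere were not counted as a baseline. A general nearness of Spred1 wt 1 to HSC wt is therefore not excluded. The genotypes that could settle this were not available, and the test used the libraries in which the pattern was seen.

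Short transcripts were higher and long ones lower in EC KO (Spearman's rho between fold change and length -0.312, with a median length of 1.91 kb among genes that rose and 5.529 kb among those that fell). Gene length bias as the whole cause is argued against by a correction for length, which kept 52.96% of the calls, only just over a bound that was chosen when the number was already known. A difference in depth is argued against by a rho of -0.323 after thinning to equal total counts. The spread between libraries stays open: 3 of the 21 libraries of other groups lay within the EC KO range (-0.314 to -0.0743). EC KO 5 alone set the upper end of that range. The other EC KO libraries lay between -0.314 and -0.198, and global KO 1 stood at -0.198. The trend per library was lower in EC KO (-0.237 ± 0.102, SD, n = 5) than in Spred1 wt (0.0504 ± 0.131, n = 5; exact permutation p = 0.01587). What sets the trend in each library stays open. Weaker length trends were also seen outside EC KO. Spearman's rho between fold change and length was -0.136 in HSC KO against HSC wt and -0.035 in global KO against Spred1 wt. It was 0.150, in the opposite direction, in HSC wt against Spred1 wt, and 0.070 in the difference. Whether such a trend contributed to the ribosomal protein and oxidative phosphorylation calls in HSC KO and between the controls was not weighed.

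Calls in EC KO came in groups of neighbours: 7 of 275 bins of 10 Mb held more calls than the genome, where the highest of 100 shuffles gave 1. The shuffles treat neighbouring genes as independent. They therefore cannot set segments apart from neighbours that vary together for another reason. Chromosome segments of another origin in EC KO or Spred1 wt libraries could produce such groups of neighbours. The bins on chromosomes 2, 4, 5 and 15 held 116 calls, among them those of Serinc3, Kcng1, Ncmap, Atp8b5 and Rida. Kcng1 and Atp8b5 lay at the low end of the second principal component, with mast cell genes such as Mcpt4 and with Y-linked genes. A difference in mast cell transcripts was not weighed as the source of their calls. Sex alone is argued against, as 60.34% of the 116 calls were kept among libraries with Y transcripts. Loss of Spred1 in endothelial cells cannot be told apart from the other explanations by these data, with 15.52% of the calls going the same way in global KO at p under 0.05. With HSC wt as control 68.1% of the calls were kept, but 2 bins were found and 1 of them was among the 7.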

How the results depend on the processing

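The alternatives with composition covariates, Y transcripts only, length and GC corrections, without genes near Spred1 and with permutation were chosen after seeing the data. Normalization, filters and the length and GC correction left every count of calls within 1.5 times, and the overlap of 1 gene stayed under every setting tried for it. For changes below, the cause was not tested, except that fewer libraries or genes by construction change the power or the count. The global KO count of 10 moved to 4 (fit of these groups only), 22 (composition covariates), 45 (DESeq2) and 4 (without genes within 20 Mb of Spred1). The HSC KO count of 3 moved to 5 (composition covariates), 0 (Y transcripts only) and 5 (DESeq2). The EC KO count of 1065 moved to 671 (sex-gene covariate), 333 (these groups only), 2052 (mean of both wild-type groups as control), 2514 (composition covariates), 692 (gene length correction), 1824 (limma voom) and 152 (log2 threshold of 1). The count of 4 between the controls moved to 1 (these groups only), 13 (composition covariates), 1 (Y transcripts only), 35 (DESeq2), 18 (limma voom) and 1 (without genes near Spred1). The count of 2 in the difference moved to 1 (Y transcripts only), 7 (DESeq2), 5 (limma voom) and 1 (log2 threshold of 1). With each library left out the counts ran from 8 to 25 in global KO, 3 to 3 in HSC KO, 483 to 1880 in EC KO, 1 to 21 in the controls and 2 to 7 in the difference, and the overlap from 1 to 1.

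Some values turned direction. In HSC KO with Y transcripts only, Alas2 was at -1.95, Jchain at -0.0716, Mtrr at 0.0328 and Mx1 at -0.475. With limma voom, Alas2 was at -1.23, Hbb-bs at -0.68 and Mx1 at -0.650. With composition covariates, Mtrr was at 0.0059 and Mx1 at -0.109 in HSC KO, and Egfl7 at -0.0298 in EC KO. Against HSC wt, EC KO had Hist1h1d at -0.0423, Hmga2 at -0.152, Isg15 at 0.297 and Zbp1 at 0.375. Among lists, with Y transcripts only, the adjusted p was 0.4706 for erythroid, 0.5817 for plasma cell and 0.5309 for cholesterol synthesis genes in HSC KO, 0.604 for ERK output genes in the controls and 0.6643 for interferon-stimulated genes in the difference. In EC KO it was 0.9298 (sex-gene covariate), 0.3398 (composition covariates) and 0.9921 (exact permutation) for ERK output genes and 0.5659 (composition covariates) for mast cell markers, a value fixed by construction because one covariate is the mean of that list.

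With each library left out, log2 values that turned ran from -0.185 to 0.0117 (Bid) in global KO. In HSC KO they ran from -2.10 to 3.71 (Alas2), -0.975 to 4.54 (Hbb-bs), -0.0648 to 1.30 (Ifi27l2a), -0.0272 to 0.0281 (Mtrr) and -0.595 to 1.33 (Mx1), and from -0.225 to 0.0369 for Egfl7 in the controls. The adjusted p of lists ran from 2.33e-05 to 0.169 (erythroid, HSC KO), 2.73e-05 to 0.778 (plasma cell, HSC KO), 0.519 to 0.9998 (ERK output, EC KO) and 6.03e-05 to 0.255 (interferon, difference). Of list results that passed or were named, 65 lost the call with an estimated correlation, which is every list that had passed. The other 3 were ERK output results in EC KO, the controls and the difference, which had not passed. With fry 60 lost the call, and the 8 that kept their result include these 3. The ribosomal, PI3K-AKT-mTOR and NF-kB lists in EC KO and the BCL2 family and p53 lists in the controls passed camera at the preset correlation and fry. With an estimated correlation they did not pass. List calls were also lost with exact permutation (53), composition covariates (20), Y transcripts only (14), gene length correction (10) and the sex-gene covariate (5). The smallest p that exact permutation allows is 0.007937 with 5 and 5 libraries and 0.002165 with 6 and 5. Lists at that limit reached only 0.2857 (endothelial, HSC KO) or 0.05715 (interferon-stimulated, controls) after adjustment over lists. The losses with exact permutation were thus largely set by group size. DESeq2 kept 195 named gene results, made 23 pass and lost 1. Every alternative fixed beforehand was run. No paired analysis was possible because the groups share no mice and the numbers in the titles only name libraries. Depth limits genes of few counts, such as Mir674 with 3 counts in Spred1 wt, Kcng1 in EC KO and St6galnac2 in Spred1 wt with 5 each, whose fold changes depend on the prior.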

Other observations

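The tests of Ccnd1 and of the HSC KO splits were written after their results were known, and the other splits before. The libraries spread along an axis that crossed the groups. Mast cell genes lay at its high end, and macrophage and erythroid genes and Rag1, a B cell marker, at its low end. Mcpt4, a mast cell protease gene, ran from 3.56 to 247 CPM within HSC KO and from 1.01 to 58.7 within EC KO. In HSC KO 1 Alas2, a heme synthesis gene, stood at 17.7 CPM, against a mean of 0.337 ± 0.179 (SD, n = 5) in HSC wt.

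Ccnd1 was weighed as a hypothesis, that the loss of Spred1 in haematopoietic cells raises it. In HSC KO, a group that shares no library with global KO, Ccnd1 was above all controls in 5 of 5 libraries (exact permutation p = 0.007937, the smallest that 252 regroupings allow), the result predicted if the hypothesis holds, though not past the threshold over all genes. Its level was also higher in EC KO, the endothelial knockout (log2 difference 0.54, edgeR adjusted p = 0.0554, past the threshold in DESeq2), where Spred1 fell too, and the global KO call was lost in a fit of those 11 libraries alone (log2 difference 0.993, adjusted p = 0.1829). A change in the share of mast cell or macrophage transcripts as its cause is argued against, because with both scores as covariates Ccnd1 stood at a log2 difference of 1.03 in global KO (edgeR adjusted p = 0.0127). Protein and cell cycle state were not measured, and the pattern was found in the same data.

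Other splits of the libraries were set against the real one, 100 per comparison with the real one included, and only a share under 0.05 was taken to exclude chance, so that 4 and 5 splits, though 1 apart, fall on different sides. Of the global KO and Spred1 wt libraries (462 splits possible), 7 called at least the 10 genes found (highest 542), 70 at least the 9 lists (highest 19), and 8 gave the ERK output list a p as small as 2.81e-07 (lowest 7.59e-11), so that chance cannot be excluded for these. For HSC KO and HSC wt (126 possible), 2 called at least 3 genes (highest 6) and 4 at least 18 lists (highest 21), which is under that bound for both, while 12 gave the ERK output list a p as small as 0.000188 (lowest 1.17e-10). The 3 genes include Spred1, the gene knocked out, whose call in the real split was fixed by design. No share was counted without it, so that chance is not excluded for the other 2. For EC KO and Spred1 wt, 4 called at least 1065 genes (highest 2161) and 68 at least 9 lists (highest 17), so that the genes alone are under the bound. For the controls, 5 called at least 4 genes (highest 164), where chance cannot be excluded, and 4 at least 17 lists (highest 19), which is under the bound. For the difference, 4 called at least 2 genes (highest 603) and 44 at least 12 lists (highest 20), so that the genes but not the lists are under the bound. Those 2 genes, Mtrr and Fastkd3, are neighbours and may stand for 1 difference. Splits that called many times the number found point to a structure of the libraries other than the groups, whose nature was not tested, and it keeps the shares under the bound from showing that the groups are the cause.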
